A study of Bos taurus with 9 samples.

How the data were processed

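Small RNA was sequenced from BoMac cells, an immortalised bovine macrophage line, in 9 libraries: 3 untreated controls, 3 from cells given poly I:C at 10 µg/ml and 3 from cells given CpG at 50 µg/ml. Per the labels, cells were plated at least 24 h before treatment and harvested after 6 h. RNA was extracted as total RNA with a Qiagen miRNeasy kit, and libraries were made with an Illumina TruSeq small RNA kit, per the labels' protocols.

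The deposited table gives whole-number read counts per mature microRNA arm and library, 1 column per library, which were not normalised. The submitters' processing notes name bcl2fastq 2.17.1.14 and Novoalign 3.06.03. The genome build, the annotation, the counting tool and the treatment of reads that map to several places were not given in the sources used here, so reads of near-identical copies cannot be assigned with certainty. Of 3938 rows, 10 repeated an earlier name with a count of 0 in each library and were left out. In the deposited counts, 4 values were written in scientific notation with 3 significant digits and were used as whole counts.

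Among the 3928 distinct rows, 222 carried a bovine miR name and 3706 carried an identifier made of a chromosome sequence and a number, in 1853 hairpins with a 5p and a 3p row each. The gene name table of the ARS-UCD2.0 assembly, searched by name alone, matched 222 of the named rows. The identifiers of the other rows are not gene names and could not match. Neither positions nor sequences were compared, so these loci may include known microRNAs. The unnamed loci are therefore given by the identifier in the table, without a gene name or coordinates. A count of 0 in each library was found for 962 rows.

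Groups came from the treatment and replicate number in the labels. The labels also tag replicates 1, 2 and 3 of each group as Expt 11, 22 and 33, without saying what the tag marks. They do not state whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 228.0, so none was taken as a copy of another library. Each was entered as 1 replicate, although separate preparations of the same RNA could differ as much.

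Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 1321 rows, 81 of them named. Libraries were scaled by the TMM method, and a quasi-likelihood model with group as the only term was fitted to the 9 libraries together. Contrasts compared poly I:C with control, CpG with control, poly I:C with CpG, and any difference among the 3 groups. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over all tested rows, and passed at an adjusted p under 0.05. Fold changes are fitted values with the standard error (SE) taken from the fold change and its F statistic. CPM values are counts scaled to the TMM-adjusted library size, and RPM values are counts scaled to the library total, given as mean ± SD. Shares of a library were compared by exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p under 0.1. Intervals are 95% exact Poisson or Clopper-Pearson intervals and cover counting error only, because reads without molecular identifiers are not independent molecules.

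In each comparison against control the rule named each row that passed and, where fewer than 10 passed, the 5 rows of lowest p in each direction, given as not passing. Because unnamed loci have no gene name, the rows of lowest p were taken among named microRNAs only. The 10 most abundant rows and members of preset lists were also part of the rule. The 22 lists covered families, toll-like receptor and interferon responses, macrophage polarisation and cell type markers. Lists, tests and alternatives were fixed before the data were examined, except where stated. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry, and 1 list qualified. Members such as miR-155, miR-146a, miR-146b, miR-132, miR-212, miR-21, miR-221 and miR-222 were not analysed here.

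The fit was tested on simulated counts for the 1321 rows, with known changes placed in 200 rows. In the comparison of poly I:C with control it called 3.57% of 2-fold, 38.4% of 4-fold and 71.8% of 8-fold changes, with 1 false call. In the comparison of CpG with control it called 6.35%, 33.8% and 72.5%, with 0 false calls. The adjusted p is easier to pass where many rows change, so these shares do not hold where few rows change. In the real comparison of CpG with control, 6 rows fitted at 7.80-fold or more did not pass.

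Alternatives were the size factors of DESeq2 1.42.0, upper-quartile factors, library totals without TMM, no count filter, a filter of at least 10 RPM in 3 libraries, the DESeq2 test, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library. The DESeq2 test used all rows with any read and its own filtering in place of filterByExpr, so its calls differ in rows as well as test. Figures were drawn with matplotlib 3.10.9. No library was left out of the reported fits.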

Results

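The study asked how small RNAs of bovine macrophages respond early to a viral and a bacterial stimulus. BoMac cells were exposed for 6 h to poly I:C, a synthetic double-stranded RNA sensed by toll-like receptor 3, or to CpG, DNA motifs sensed by toll-like receptor 9. Each condition and the untreated control had 3 libraries. Total counts ran from 17585249 to 31472315 per library, 217985254 in all, and 1196 to 2344 rows were detected per library.

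Most reads of BoMac cells came from a few loci that carry no microRNA name in the table. AC_000176.1_29510-5p held 38.2% ± 2.79 (SD, n = 3) of control reads, and AC_000161.1_7119-5p held 15.4% ± 3.56. The 10 most abundant rows together took 77.3% ± 1.36 of control reads, against 84.7% ± 9.61 with poly I:C and 77.4% ± 7.19 with CpG. The exact permutation test gave p = 0.3 and p = 1 (n = 3 per group), in a design that cannot go below p = 0.1. The difference of poly I:C from control was 7.32 percentage points, 2.13 without poly I:C replicate 3 and 11.6 without poly I:C replicate 1, and that of CpG was 0.0413, between -3.38 and 3.78 with a library left out. The share of AC_000176.1_29510-5p was 34.3% ± 0.907 with CpG, below control in each library (exact permutation p = 0.1, the smallest this design allows). The test of this single row was not planned. Its share also depends on that of AC_000161.1_7119-5p. In replicates 1, 2 and 3 the latter was 16.8%, 11.4% and 18.1% in control and 10.1%, 19.5% and 30.3% with CpG. Whether AC_000176.1_29510-5p differs among the reads outside that locus was not tested. With poly I:C its share was 27.0% ± 18.6 (exact permutation p = 0.5). Poly I:C replicates 1, 2 and 3 had 41.7%, 33.1% and 6.04%, and the mean without replicate 3 was 37.4%.

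Rows with a miR name held 2.06% ± 0.0973 of control reads, 1.36% ± 0.797 with poly I:C (1.80% without replicate 3) and 2.22% ± 0.828 with CpG. The most abundant of them was miR-99b, which is encoded in a cluster with let-7 and miR-125 genes, at 7201 ± 1177 RPM (reads scaled to the library total, without TMM) in control libraries. It was followed by miR-27a-3p, of the miR-23-27-24 cluster, at 3041 ± 260 and by miR-30c at 2356 ± 405 RPM. Counts under a microRNA's name do not bound its level in the cells, because most reads lay at unnamed loci that were not matched to microRNAs. The miR-142, miR-150, miR-223 and miR-363 rows, markers of blood and myeloid cells, summed to 48 reads in all 9 libraries. In the order miR-142-5p, miR-142-3p, miR-150, miR-223 and miR-363, control libraries had 1, 5, 0, 0 and 3 reads. Poly I:C libraries had 1, 6, 0, 2 and 0, and CpG libraries had 7, 8, 7, 4 and 4. These rows did not pass the count filter and were not tested. MiR-223, abundant in primary myeloid cells, had 6 reads, or 0.0275 RPM (95% Poisson interval 0.0101 to 0.0599). Of the red blood cell markers, miR-451 had 170 reads in all, 58 in control, 48 in poly I:C and 64 in CpG libraries, and miR-144 had 2. The row of the epithelial marker miR-141 had 0 reads, which allows that row up to 0.0169 RPM at the 95% Poisson bound.

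Poly I:C replicate 3 stood apart from the other 8 libraries. AC_000161.1_7119-5p took 80.3% of its reads, against 10.1% to 30.3% elsewhere, with 95% Clopper-Pearson intervals no wider than 0.0375 percentage points. It had 1196 rows detected, and 5741641 reads lay outside that locus. Its log CPM correlated with the other libraries across rows at r = 0.813 to 0.881, while the other 8 correlated with each other at 0.958 to 0.990. Rows are not independent replicates. The TMM factor was 0.241 for this library and 0.901 to 1.64 for the others.

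**Figure D1:**
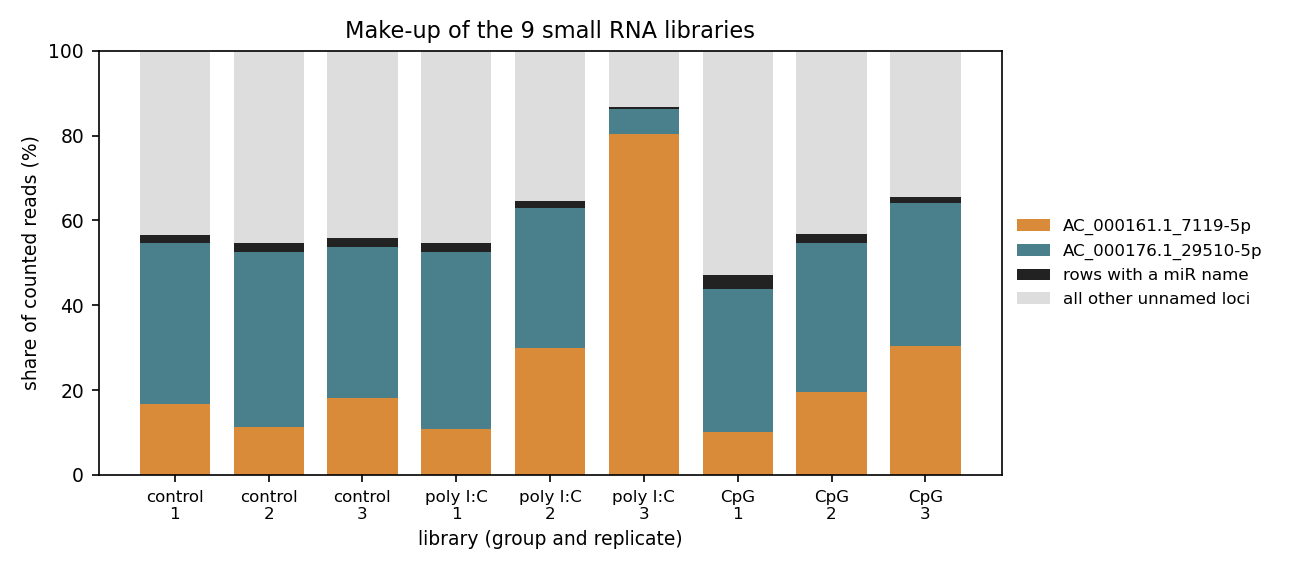
Share of counted reads (%) in each of the 9 libraries, stacked for AC_000161.1_7119-5p, AC_000176.1_29510-5p, all rows with a miR name and all other loci. AC_000161.1_7119-5p takes 80.3% of poly I:C replicate 3 and 10.1% to 30.3% of the others.

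The comparison of poly I:C with control asked which small RNAs changed after the viral mimic. AC_000176.1_31800-5p rose 9.58-fold, from 2.90 ± 0.162 CPM in control to 27.9 ± 8.23 CPM with poly I:C (n = 3 per group), and each poly I:C library lay above each control library. With CpG the same locus had 3.59 ± 0.712 CPM. Its raw counts were 85, 114 and 73 in the control libraries and 685, 534 and 262 in the poly I:C libraries. It was the only row of 1321 that passed edgeR's test (log2 fold change 3.26, SE 0.39, adjusted p = 0.00703), and 64 rows had an unadjusted p under 0.05. Without any change, about as many of 1321 rows would be expected under 0.05 if p-values spread evenly. The same fit gave 7 such rows for CpG against control, so its p-values may not spread evenly. The 64 rows therefore cannot be read as the number without change. DESeq2 and limma-voom each called 1 row. Over 20 alternatives the fitted log2 fold change lay between 2.53 and 3.37, and the adjusted p between 4.46e-19 and 0.931. The call ended without any 1 of the control replicates 1, 2 and 3 (log2 fold change 3.27, 3.21 and 3.11), in a fit of the 2 groups alone (3.18) and without TMM scaling (2.53).

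No named microRNA passed in this comparison, where the lowest adjusted p of a named row was 0.929. The fitted values of lowest p above control were those of miR-2362 (log2 fold change 3.02, SE 0.94) and miR-7863 (1.80, SE 0.75), the 2 named rows with an unadjusted p under 0.05. MiR-378d was fitted at 1.49 (SE 0.71), miR-2340 at 1.25 (SE 0.60) and miR-27a-5p at 1.12 (SE 0.52). For these, replicate 3 set most of the mean: miR-2362 had 0.554, 1.39 and 7.98 CPM in poly I:C replicates 1, 2 and 3. MiR-27a-5p had 443, 750.5 and 2096 CPM there. On the low side were miR-433 at -0.62 (SE 0.34), miR-1224 at -1.35 (SE 0.78), miR-6535 at -0.71 (SE 0.53), miR-324 at -0.53 (SE 0.41) and miR-574 at -0.47 (SE 0.38). With a library left out, miR-1224 ranged from -2.09 to -0.92 and miR-324 from -0.86 to -0.25. Without poly I:C replicate 3, 1 row passed and no named microRNA did.

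The comparison of CpG with control asked the same for the bacterial mimic. No row passed edgeR's test among 1321, and limma-voom gave 0 calls. By edgeR 7 rows had an unadjusted p under 0.05, fewer than expected without any change if p-values spread evenly. DESeq2, run on all rows with any read, called 4 rows, all higher with CpG. AC_000187.1_43809-5p had 0.483 ± 0.230 CPM in control and 3.82 ± 0.242 CPM with CpG (log2 fold change 2.96, SE 0.62, adjusted p = 0.281 by edgeR), higher in each CpG library than in each control library. AC_000180.1_36255-5p had 0.106 ± 0.0720 CPM in control and 1.43 ± 0.266 CPM with CpG (log2 fold change 3.69, SE 0.75, adjusted p = 0.281 by edgeR). Both loci passed without poly I:C replicate 3, when 4 rows were called, and in a fit of the CpG and control libraries alone, when 6 were. In these 2 fits the log2 fold change of AC_000187.1_43809-5p was 2.97 and 2.96, with an SE of 0.41 and 0.42. Over 20 alternatives the adjusted p of AC_000187.1_43809-5p lay between 0.000578 and 1.00 and that of AC_000180.1_36255-5p between 0.00962 and 1.00.

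Named microRNAs did not pass after CpG, and their lowest adjusted p was 1.00. MiR-3533 was the named row of lowest p (log2 fold change 1.96, SE 0.74, unadjusted p = 0.0238 by edgeR), at 0.160 ± 0.0894 CPM in control and 0.640 ± 0.343 CPM with CpG. The other named rows of lowest p above control were miR-449d at a fitted 2.20-fold (log2 SE 0.62), miR-2451 at 2.59-fold (log2 SE 0.92), miR-377 at 2.29-fold (log2 SE 0.84) and miR-2362 at 2.20-fold (log2 SE 0.91). Below control, on the log2 scale, were miR-2284f at -0.84 (SE 0.54), miR-2307 at -0.43 (SE 0.30), miR-217 at -1.08 (SE 0.78), miR-4523 at -1.01 (SE 0.94) and miR-1301 at -0.93 (SE 0.89). Control replicate 2 set most of the control mean of miR-4523 (13, 60 and 14 reads in control replicates 1, 2 and 3), whose log2 fold change was -0.28 without that library and -1.61 without CpG replicate 2. That of miR-2284f was -1.45 without CpG replicate 2. Under 21 alternatives of the 3 pairwise comparisons, and 20 of the test among the 3 groups, 0 named microRNAs passed.

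**Figure D2:**
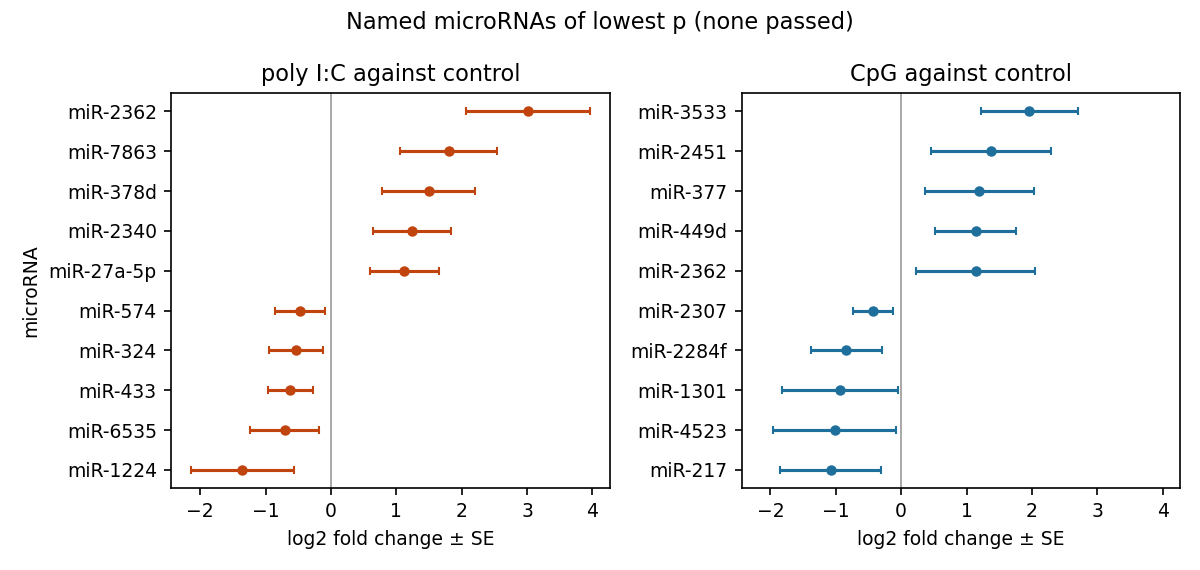
Fitted log2 fold change ± SE (edgeR, 3 libraries per group) of the named microRNAs of lowest p in each direction, for poly I:C and CpG against control. None passed, and the bars span up to 0.94 on the log2 scale.

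The direct comparison of poly I:C with CpG, at the doses given, separated the same loci. AC_000176.1_31800-5p was 7.75-fold higher with poly I:C (log2 fold change 2.95, SE 0.38, adjusted p = 0.0154 by edgeR). AC_000187.1_43809-5p was lower with poly I:C (log2 fold change -4.35, SE 0.70, adjusted p = 0.0394 by edgeR), with 12 reads in the poly I:C libraries and 306 in the CpG libraries. AC_000180.1_36255-5p was lower too (adjusted p = 0.0394 by edgeR), with 1 read in the poly I:C libraries against 116, a ratio of CpG to poly I:C of 86.4 (95% exact interval 15.2 to 3442, counting error only). These were the 3 rows called. Of named microRNAs, miR-1301 (log2 fold change 2.44), miR-2284f (1.31) and miR-7863 (1.71) had an unadjusted p under 0.05 and did not pass. Poly I:C replicate 3 set most of the mean of miR-1301, with 0.587, 0.315 and 3.85 CPM in poly I:C replicates 1, 2 and 3, and of miR-7863, with 2.41, 3.69 and 20.95 CPM. With any control or CpG library or poly I:C replicate 2 left out, the count was 0, without poly I:C replicate 1 it was 1 and without poly I:C replicate 3 it was 4. With each library left out in turn the fitted log2 fold change stayed between 2.68 and 3.05 for AC_000176.1_31800-5p and between -4.61 and -4.06 for AC_000187.1_43809-5p. That of AC_000180.1_36255-5p, with 1 read in the poly I:C libraries, moved between -8.19 and -5.59. The 2 groups alone gave 0 calls with edgeR, as did library totals without TMM, and DESeq2 called 6. With the replicate number as a block, which applies if the shared numbers mark shared experiments, 1 row passed, and neither AC_000187.1_43809-5p (log2 fold change -4.33) nor AC_000180.1_36255-5p did.

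**Figure D3:**
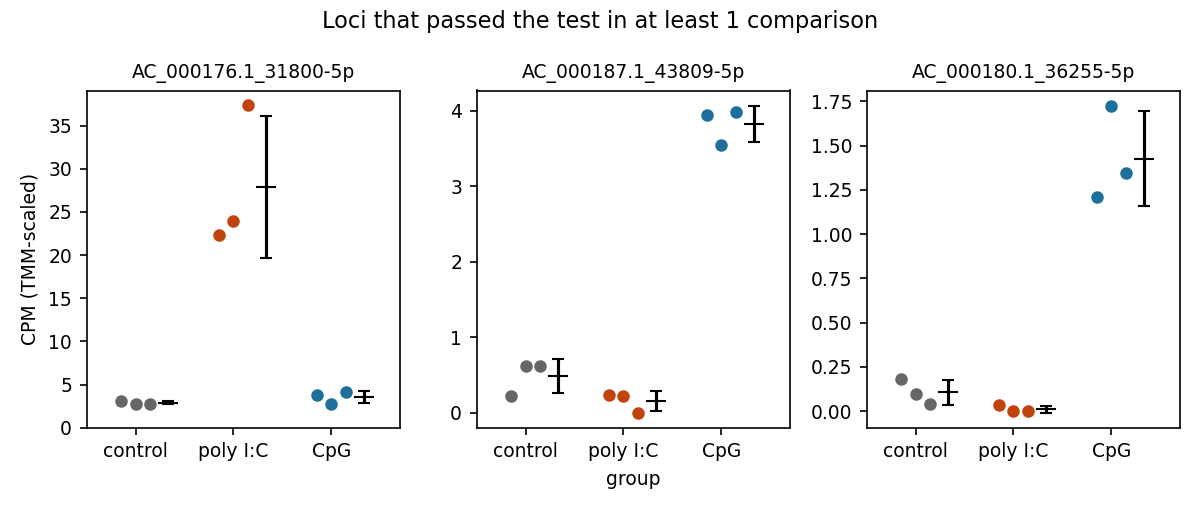
CPM (TMM-scaled) of the 3 loci that passed in at least 1 comparison, by group, with a point per library and the mean ± SD in black. The poly I:C libraries of AC_000176.1_31800-5p lie above the other 6, and the CpG libraries of AC_000187.1_43809-5p and AC_000180.1_36255-5p lie above the other 6.

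The test for any difference among the 3 groups called the same 3 loci (lowest adjusted p = 0.00383 by edgeR). An unadjusted p under 0.05 was found for 42 rows, fewer than expected without any change if p-values spread evenly. DESeq2 called 9 and limma-voom 4. The count was 1 without any of the control or CpG libraries or poly I:C replicates 1 or 2, and 5 without poly I:C replicate 3. It was 1 with the replicate number as a block.

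Of the 22 lists, 14 had a row with a member's name, and 1 reached 3 tested members. That list held microRNAs of an imprinted region, expressed from the maternal chromosome, with 5 tested members: miR-1185, miR-136, miR-377, miR-431 and miR-433. None passed in either treatment, over all rows or adjusted over the list alone. With poly I:C 4 were fitted higher and 1 lower (camera p = 0.598, p = 0.621 with an estimated correlation), and with CpG 2 higher and 3 lower (camera p = 0.251, p = 0.308 with an estimated correlation). With CpG the median of the members lay below 0 (log2 -0.04) while their mean and the test lay above (log2 0.24). MiR-136 had 10.4 ± 2.33 CPM in control, 15.8 ± 1.07 CPM with poly I:C and 11.8 ± 2.51 CPM with CpG.

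Smaller lists could only be described by their members. The toll-like receptor and NF-kB response list had 1 tested member, miR-99b, at 5956 ± 1210 CPM in control, 6782 ± 2728 CPM with poly I:C and 6601 ± 1109 CPM with CpG. The macrophage polarisation list had both arms of miR-27a. MiR-27a-3p had 2501 ± 146 CPM in control, 1838 ± 1015 CPM with poly I:C and 2502 ± 667 CPM with CpG. MiR-27a-5p had 503 ± 71.2, 1096 ± 879 and 782 ± 282 CPM. The interferon-beta response list had miR-30c, at 1930 ± 226 CPM in control and 1226 ± 853 CPM with poly I:C, and miR-431, at 18.4 ± 4.79 and 19.5 ± 2.91 CPM. Of the miR-17-92 family clusters, miR-18a had 94.1 ± 32.8 CPM in control, 77.5 ± 67.0 CPM with poly I:C and 84.0 ± 21.4 CPM with CpG. MiR-19a, also on the list of toll-like receptor pathway repressors, had 88.3 ± 27.7, 85.0 ± 65.8 and 94.1 ± 29.4 CPM. Without poly I:C replicate 3 the poly I:C mean was 5215 CPM for miR-99b, 2410 for miR-27a-3p, 597 for miR-27a-5p, 1666 for miR-30c, 111 for miR-18a and 120 for miR-19a, so that the side of the control mean turned for miR-99b, miR-18a and miR-19a. None of these passed in any comparison.

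Across the 1321 rows, the log2 fold changes of poly I:C and of CpG against control correlated at r = 0.328 (rho = 0.424), with a covariance of 0.154. Simulated groups without any change, with simulated controls, gave r = 0.487 ± 0.0344 and a covariance of 0.266. With these rows the observed values lay below those of the simulated groups. All 9 libraries were simulated with 1 spread per row, estimated with poly I:C replicate 3 included. Over all rows that spread, the common dispersion, was 0.283 with this library and 0.132 without it. The simulated controls may vary more than the real ones, so the simulations cannot tell whether the observed values are low or high. Among the 444 rows with at least 10 RPM in 3 libraries, r was 0.620 against a simulated 0.504 ± 0.0590, and the covariance was 0.131 against 0.160 ± 0.0261. Rows are not independent replicates.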

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

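Of the tests here, the covariate for the share of AC_000161.1_7119-5p, the robust dispersion and the fit without poly I:C replicate 3 with the block were chosen only after the results were seen. Calls are given for poly I:C against control, CpG against control, poly I:C against CpG and any difference among groups, reported as 1, 0, 3 and 3. Library totals without TMM gave 0 calls in each, and moved the median log2 fold change of poly I:C against control from -0.11 to -0.54. The filter of 10 RPM in 3 libraries, set on library totals without TMM, removed the 3 called loci and also gave 0 in each. No count filter gave 10, 0, 4 and 25. The DESeq2 test gave 1, 4, 6 and 9. A fit of only the 2 groups compared gave 0, 6 and 0 for the pairwise comparisons. The covariate gave 1, 1, 4 and 5. Leaving out poly I:C replicate 3 with the replicate block gave 1, 5, 5 and 6. Leaving out each library gave 0 to 1, 0 to 4, 0 to 4 and 1 to 5. Size factors of DESeq2, upper-quartile factors, limma-voom and the robust dispersion kept each count within 1.5 times. The common dispersion, the spread between replicates over all rows, was 0.283 with 9 libraries and 0.132 without poly I:C replicate 3. In CpG against control, the SE of AC_000187.1_43809-5p fell from 0.62 to 0.41 without that library. Its log2 fold change was 2.96 and 2.97, so its call came with a smaller spread and not a larger change. Apart from this and the removed loci, the cause was not tested.

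The replicate block gave 1, 0, 1 and 1 calls. The labels tag replicates 1, 2 and 3 of each group Expt 11, 22 and 33 without saying what the tag marks. Deviations correlated above 0.1 in 6 of 9 same-number pairs (r = -0.0379 to 0.409) against 3 of 18 other pairs (r = -0.496 to 0.522). The highest r of all was between different numbers, control replicate 2 and poly I:C replicate 1. Of 9 libraries, 6 correlated best with their own number, a hint of pairing that did not hold in every pair.

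The correlation of the fold changes was 0.620 with the 10 RPM filter (0.504 ± 0.0590 in simulated unchanged groups under that filter, highest 0.632) and 0.127 to 0.484 with a library left out, and the cause was not tested. List tests gave p between 0.0844 and 0.989 under the alternatives. The difference from control in the share of the 10 most abundant rows moved by less than 1 SD of the treated libraries. That SD was 9.61 percentage points with poly I:C, replicate 3 included, and 7.19 with CpG, a wide limit. Without poly I:C replicate 3 the poly I:C difference fell from 7.32 to 2.13 points. Of 844 values of single rows under the alternatives, 3 had the opposite sign, none of them called. Depth limits loci such as AC_000180.1_36255-5p, with 1 read in the poly I:C libraries.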

Other observations

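The tests of arm ratios, of loci that track AC_000161.1_7119-5p, of poly I:C treatment and of a shift shared across groups for replicate 3, of library scaling and of the arm suffix were chosen only after the results were seen. Thinning for replicate 3 and the test of a single source of reads were also set for patterns first seen in the counts. MiR-27a and miR-331 hairpins gave reads from both arms. The ratio of 5p to 3p reads of miR-27a was 0.217, 0.167 and 0.219 in the control libraries, 0.168, 0.343 and 3.01 in poly I:C replicates 1, 2 and 3, and 0.160, 0.332 and 0.537 in CpG replicates 1, 2 and 3. That of miR-331 was 0.386 to 0.477 in control, 3.19 in poly I:C replicate 3 and 0.280 to 0.674 in the other 5 treated libraries.

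AC_000161.1_7119-5p ranged 13.1-fold in count, from 1778522 to 23364248. Of the other 1320 tested rows, 15 held a ratio to it with a SD under 0.5 on the log2 scale across the 9 libraries, against a median SD of 2.08. None of the 15 had a miR name, and the most abundant held 5.88% of the count of AC_000161.1_7119-5p.

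Poly I:C replicate 3 differed from the control mean by a median of 1.92 on the log2 scale across 1321 rows. Whether it shares a response with the other poly I:C libraries stays open: across rows its deviation from the control mean correlated with that of poly I:C replicate 1 at r = -0.300 and of replicate 2 at 0.414, and with those of CpG replicates 1, 2 and 3, taken from the same controls, at -0.0224, 0.0826 and 0.460. Fewer reads outside the dominant locus is argued against by thinning: at 5741641 reads each, the lowest of the other 8 libraries still detected 1.47 times as many rows. A shift of small RNA content shared across groups may contribute, since the deviation correlated with CpG replicate 3 minus CpG replicates 1 and 2 (r = 0.409) and with control replicate 3 minus control replicates 1 and 2 (r = 0.386). What such a shift comes from was not tested.

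In the comparison of CpG with control, 6 rows at 5 loci had an unadjusted p under 0.05 and at least a 4-fold higher fitted level, with 96 reads in control, 39 in poly I:C and 910 in CpG libraries. Library scaling moves all rows alike, and on library totals without TMM the median log2 fold change of 1321 rows was 0.044. With TMM the 6 rows were fitted at 2.96 or more, so a shift common to all rows was small beside them. On library totals the 95th percentile of all rows was 0.85. The 6 rows were picked as high in this comparison, so lying above that percentile is no test. A single source of reads, such as carry-over of a common RNA or DNA, could not be decided: the rows did not keep 1 ratio across the CpG libraries (chi-square per degree of freedom 5.22), but 1000 random sets of 6 rows of similar count had a median of 6.26. A response to CpG stays open as the hypothesis named by the design.

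Among unnamed loci with at least 10 reads over both arms, the 5p row held more reads in 91.9% of 1668 pairs, against 26.7% of 15 named hairpins (Fisher's exact test, two-sided p = 1.11e-09). The suffix of unnamed loci may mark the more abundant product and not the 5' arm of the hairpin. No biological explanation was tested.

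Other splits of the libraries were counted for each comparison. For poly I:C against control, 1 of the 10 splits of the 6 libraries gave as many calls (real value 1, highest other 0). For CpG against control, 10 of the 10 splits gave as many (real value 0, highest other 0). With a real value of 0 any split gives as many, so this count decides nothing. For poly I:C against CpG, 1 of the 10 splits gave as many (real value 3, highest other 0). With 10 splits the share cannot fall under 0.05. For any difference among the 3 groups, 1 of 100 drawn splits, the real one, gave 3 calls and the highest other gave 1. Chance is not excluded by this, because the splits assume that libraries can be exchanged freely, which shared replicate numbers would limit. With the replicate block, or without any 1 of the libraries other than poly I:C replicate 3, the count was 1, and no splits were run for those fits.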
